A study of Homo sapiens with 116 samples.

How the data were processed

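Whole-transcriptome RNA sequencing had been carried out on tumour tissue labelled as squamous cell lung carcinoma, a lung cancer that carries features of stratified epithelium. The labels describe 116 libraries and place all of them in 1 group. They give the histology under a tag for cell lines, while their protocols describe tumour tissue, and the libraries were treated as tumour tissue. Per the labels' protocols, DNA and total RNA were purified together from homogenised tumour tissue with a column kit, and 100 ng of RNA treated with DNase entered a strand-specific library kit for total RNA. Such a kit keeps transcripts without a poly(A) tail, so small nuclear and mitochondrial RNA take part of the counts. A targeted DNA panel that the series' design text names was not analysed here. The labels name no treatment, no normal tissue and no batch. Nothing in them says whether the libraries came from separate donors. The p-values of correlations and slopes thus measure the spread between these libraries, while those of the list tests compare genes.

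The authors deposited expected counts per gene model, and 4.94% of the deposited values are not whole numbers. Per the submitters' processing notes, the tools were cutadapt 1.8.1, STAR 2.5.3a, RSEM and HTSeq, with no role or order stated, and the versions of RSEM and HTSeq are not given in the sources used here. Expected counts divide a read that fits several genes among them, so the values of near-identical genes are uncertain. This applies to SFTPA1 and SFTPA2, SIK1B, F8A2, the AKR1C, UGT1A, SPRR2, MAGEA, keratin 6, tryptase, haemoglobin, immunoglobulin and HLA genes, CYP4F3 and CYP4F11, TRIM16L and CGB5. Whether the counting used the strand is not given in the sources used here, so genes that overlap an antisense partner are uncertain too. The notes name the genome builds hs37d5 and GRCh38 without saying which was counted on. No coordinates are therefore printed, and genes carry the symbol and identifier of the deposited table.

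The table held 63357 gene models, each with a name. XIST and the Y-linked genes (570 gene models) were taken out before any step and the other 62787 were analysed, of which 46179 had a count in any library. Expected counts were rounded to whole numbers. The 24929 genes with at least 10 counts in at least 12 libraries were kept for the slopes and the scores. Normalised expression is given as CPM, counts scaled to a common library total, with edgeR 4.0.16 TMM factors, and log2 CPM uses a prior count of 2. CPM takes no account of transcript length, so levels are compared between libraries and not between genes. Library totals ranged from 10049224 to 154946394 expected counts, and the 15 libraries of the early shallow block averaged 15573722. A gene at 1 CPM thus rests on about 10 counts in the shallowest library. Of the 6670 pairs of libraries, 0 held identical counts. The closest pair differed by a chi-square of 92.8 per degree of freedom (median 630), so no library was counted as a repeat of another.

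Before the data were examined, 38 gene lists were fixed: 8 tumour programmes, 6 immune programmes, 15 cell types and 9 chromosome regions. Another 18 recurrently altered genes were to be described singly. Of 530 list genes, 529 matched a gene model, 1 of them through an older symbol, and PECAM1 was not analysed here. LORICRIN, SSX1, CALCA, HBD, AHSP and CA1 had too few counts. The remaining 523 were measured, 380 of them with a median of at least 5 CPM. A list's score is the mean of its members' z-scored log2 CPM. Lists among the 500 most variable genes (SD of log2 CPM, mean CPM of at least 5, 12015 background genes) were tested with a one-sided Fisher's exact test. That test takes genes as independent, while members of a list vary together, so its p-values may be too small. Co-variation is the mean pairwise Spearman correlation of a list's members across libraries, tested one-sided against 10000 random lists matched on mean expression in 20 bins, so that 0.0001 is the smallest p they can give.

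The 24 pairs of measures, also fixed beforehand, were tested with Pearson's r and Spearman's rho, each by a two-sided permutation test with 100000 resamples, for which 1e-05 is the smallest p. A measure counted as falling into separate clusters when a Gaussian mixture of 2 components (mclust 6.1.1) had a BIC better by over 10 than that of 1 component, with 2 modes and at least 6 libraries in the smaller cluster. Correlations were then computed within clusters only, which made 39 correlations in the family. Every family of p-values was adjusted by the Benjamini-Hochberg method.

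For 4 scores (NRF2 targets, cornified differentiation, T cells, proliferation), the slope of each gene's counts on the score was tested with edgeR's quasi-likelihood test, in log2 change per SD of the score. The NRF2 score fell into separate clusters, so its fit had the cluster as a term and its slopes hold within clusters. No fit had a term for clusters of the other lists, so slopes of their members can include a step between those clusters. A gene outside the score's own list was called at an adjusted p under 0.05 and a log2 change of at least 0.5 per SD. Lists were tested along each score with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with an estimated correlation. A list's count is also given with p adjusted over the list alone. The score of a programme shares libraries with all genes it is compared with, so the slopes describe genes that vary together and carry no direction of cause. Each fit was repeated with 6 random reorderings of the score. Slopes on the NRF2 score were also simulated from these libraries on 24898 genes and fitted without the cluster term. The rates found thus do not describe the power of the reported NRF2 slopes, which hold within clusters. Of 100 genes given a log2 change of 1 per SD, 99% were recovered, and 77% of 100 given 0.5. The genes given a change all had a mean CPM of at least 1. Recovery of lower genes was thus not measured, and every simulated call below that level was false by construction. Of 235 simulated calls 59 were false over all genes, and 8 of 184 at a mean CPM of at least 1. For that reason these shares cannot be compared with each other. Calls by edgeR at low counts or resting on a few libraries are reported beside limma's call on log2 CPM.

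Blocks of libraries were found after the data were seen, in the order of the library names. The totals dropped after library 17 and rose again after library 32, and some RNAs differed after library 60. The blocks are called the early deep block (45 libraries), the early shallow block (15) and the late block (56). The early deep block lies on both sides of the early shallow block. The labels do not name them. Relations between measures are given within each block, with 6 libraries as the least a block must hold. Other alternatives were DESeq2 1.42.0 size factors and its Wald test, a prior count of 0.25, no count filter, median scores, library total and mitochondrial share as covariates, and leaving out the 2 libraries farthest from the median. Limma, a mean CPM minimum of 1, the block as a covariate and leaving out the 15 libraries of the early shallow block were added after seeing the data.

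Genes named along a score were, by a rule set beforehand, the 12 with the largest positive and the 8 with the largest negative slope among called genes with a mean CPM of at least 5, outside immunoglobulin and T cell receptor segments. The 20 most variable genes by the same limits were named as well, and any member of a fixed list could be named for its list. The tests ran in R 4.3.3.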

Results

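Total RNA of squamous cell lung carcinoma libraries was measured, in expected counts per gene. The labels put all libraries in 1 group, so no condition was compared with another. The data address how far gene groups vary between tumours, which of them vary together, and which genes follow 4 programmes fixed beforehand. Library totals averaged 51263906 ± 20295829 expected counts (SD over all libraries; median 52793543; range 10049224 to 154946394). Nuclear and mitochondrial protein-coding genes took 76.7% ± 4.78 of the counts. Mitochondrially encoded RNA took 19% ± 4.96, the small nuclear RNA RN7SK, a regulator of transcription elongation, 4.85% ± 2.5, and immunoglobulin genes 1.88% ± 2.19 (all SD). In the order of the library names, 3 blocks differed in technical measures. The early deep block averaged 59075315 counts (n = 45), the early shallow block 15573722 (n = 15) and the late block 54546751 (n = 56). Some RNAs, named after their values were seen, shifted with the block. The small cytoplasmic RNA RNY1 was 3.84 log2 higher in the late block than in the early blocks (SE 0.20), the small nucleolar RNA SNORD36A fell by 3.39 (SE 0.29), and the ribosomal protein gene RPS14 was 1.36 log2 higher (SE 0.12).

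Genes of squamous identity differed widely in level between libraries. TP63 (ENSG00000073282.14_1), the transcription factor that maintains the basal cells of stratified epithelium, had a median of 777 CPM (5th to 95th percentile 8.84 to 2814; log2 CPM 9.03 ± 2.35, SD). KRT5, a keratin of basal cells, had a median of 1494 CPM (5.12 to 4205), and SOX2, a lineage transcription factor, 96.6 CPM (2.58 to 525). The 18 genes chosen as recurrently altered in this cancer differed in spread. The tumour suppressor CDKN2A had a median of 11.4 CPM with a log2 SD of 3.12 and a 5th percentile of 0.043 CPM. The histone methyltransferase gene KMT2D had the narrowest spread of the 18 (median 178 CPM, log2 SD 0.32), followed by CUL3 (97.7 CPM, SD 0.47). NFE2L2, which encodes the oxidative stress regulator NRF2, had a median of 194 CPM (SD 0.94), and KEAP1, whose product targets NRF2 for degradation, 37.5 CPM (SD 0.74). EGFR had a median of 299 CPM (SD 1.26), CCND1 222 CPM (SD 0.94), MYC 188 CPM (SD 0.89) and PIK3CA 54 CPM (SD 0.64). TERT, the catalytic subunit of telomerase, had a median of 0 CPM and a 95th percentile of 0.695 CPM, a level that these depths resolve poorly.

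Genes of squamous differentiation, lung epithelium and oxidative stress defence were enriched among those that varied most between tumours. SFTPC, a surfactant protein of alveolar cells, varied most (log2 SD 4.57; median 25.9 CPM, 5th to 95th percentile 0.106 to 1361). It was followed by the cancer testis antigen MAGEA4 (SD 4.54), the urothelial membrane protein UPK1B (SD 4.47) and the cornified envelope protein SPRR3 (SD 4.41). Others among the 20 were the neuropeptide precursor NTS (SD 4.33), the calcium-binding protein CALB1 (SD 4.33), the alcohol dehydrogenase ADH7 (SD 4.27), the glutathione transferase GSTM1 (SD 4.21), the WNT antagonist SOST (SD 4.07), the keratin KRT14 (SD 4.0) and the club cell protein SCGB1A1 (SD 3.97). SIK1B, F8A2, UGT1A7, SFTPA1, SFTPA2, CASP14, SPRR2E, LINC01206 and ENSG00000231683 completed them with SDs from 3.97 to 4.34, against a median of 0.686 over the 12015 genes compared. SFTPA1 with SFTPA2, SIK1B, F8A2, UGT1A7, MAGEA4 and SPRR2E share sequence with close relatives, and their values are uncertain. Among the 500 most variable genes, 79 were immunoglobulin or T cell receptor segments. Of 24 cornified differentiation genes in the background 21 were among the 500 (1 expected by chance; one-sided Fisher's exact test, adjusted p = 4.59e-25 over 38 lists). The same held for 13 of 16 squamous identity genes (adjusted p = 9.15e-15), 11 of 12 alveolar genes (8.53e-14), 10 of 11 secretory airway genes (1.44e-12) and 11 of 30 NRF2 targets (1.18e-07). Of the red blood cell genes 3 of 3 were among them (adjusted p = 0.000454), of the cancer testis antigens 2 of 2 (0.00938), of the neuroendocrine genes 2 of 3 (0.0240) and of the plasma cell genes 3 of 10 (0.0292). The background held only 2 of 12 measured cancer testis antigens and 3 of 11 neuroendocrine genes. A gene low in most libraries reaches a mean CPM of 5 only through a few high libraries, which also give it a large SD. The results of these 2 lists are thus partly set by that limit. It also acts on low members of other lists. Examples are the cornified genes CDSN, TGM3 and DSG1 (medians of 0.355, 0.415 and 0.61 CPM) and the NRF2 target ABCC2 (0.584). The background held 24 of 28 measured cornified genes, 30 of 31 NRF2 targets and 3 of 4 red blood cell genes. All 16 squamous identity, 12 alveolar and 11 secretory airway genes were in it. The other 29 lists had an adjusted p of 0.0604 or above, and the proliferation, interferon and chromosome 3q26-q29 lists had 0 members among the 500.

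Members of the fixed lists co-varied across the tumours more than random genes on average, though single members did not follow their list. All 38 lists had a mean pairwise Spearman correlation above that of random lists (one-sided, 10000 lists, adjusted p of 0.0266 or below). It was highest for alveolar epithelium (0.878, 12 genes), fibroblasts (0.776, 18 genes), plasma cells (0.738), MHC class II presentation (0.728), red blood cells (0.718), T cells (0.717), macrophages (0.711) and NRF2 targets (0.705, 31 genes). Type I interferon response genes had 0.627, proliferation genes 0.606, squamous identity genes 0.515 and cornified differentiation genes 0.453. Cytotoxic lymphocytes (0.583), immune checkpoints (0.511), chemokines of tertiary lymphoid structures (0.527), ciliated airway epithelium (0.573), endothelium (0.553), mast cells (0.532), neutrophils (0.480) and secretory airway epithelium (0.479) lay between, as did the interferon gamma response (0.605), MHC class I presentation (0.593) and cytosolic ribosomal proteins (0.507). Hypoxia genes had 0.393, cancer testis antigens 0.368 and oxidative phosphorylation genes 0.299. Neighbours on chromosome arms that are often gained or lost in this cancer co-varied as well. The 21 genes of 3q26-q29, an amplified region, had 0.559. The closest to the list's score were DCUN1D1 (correlation with it 0.910), FXR1 (0.897) and ACTL6A (0.886), while GNB4 had -0.064. The carboxypeptidase gene CPM in 12q15 (-0.318), the neuroendocrine gene DDC (0.009) and SCARF2 in 22q11 (0.029) did not follow theirs either, and these members were chosen after their values were seen. The 8p11 genes had 0.479, with BAG4 (0.833) and LSM1 (0.812) nearest and FGFR1 at 0.308. The 4 genes of 9p21, which holds CDKN2A, had 0.50, those of 5p 0.423, of 8q24 0.391, of 7p11 0.339, of 22q11 0.254, of 11q13 0.241 and of 12q15 0.203. The neuroendocrine genes had the lowest value, 0.082 against a median of 0.031 for random lists (adjusted p = 0.0266). Within the 3 blocks the values differed for several lists. The early shallow block had lower ones, among others, for ciliated airway epithelium (0.294 against 0.573), red blood cells (0.391 against 0.718), smooth muscle (0.155 against 0.416), B cells (0.403 against 0.635), proliferation (0.405 against 0.606) and hypoxia (0.228 against 0.393). It had higher ones for 11q13 (0.439 against 0.241), 8p11 (0.634 against 0.479) and 9p21 (0.691 against 0.50), while the early deep block had 0.328 for 8p11.

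**Figure D1:**
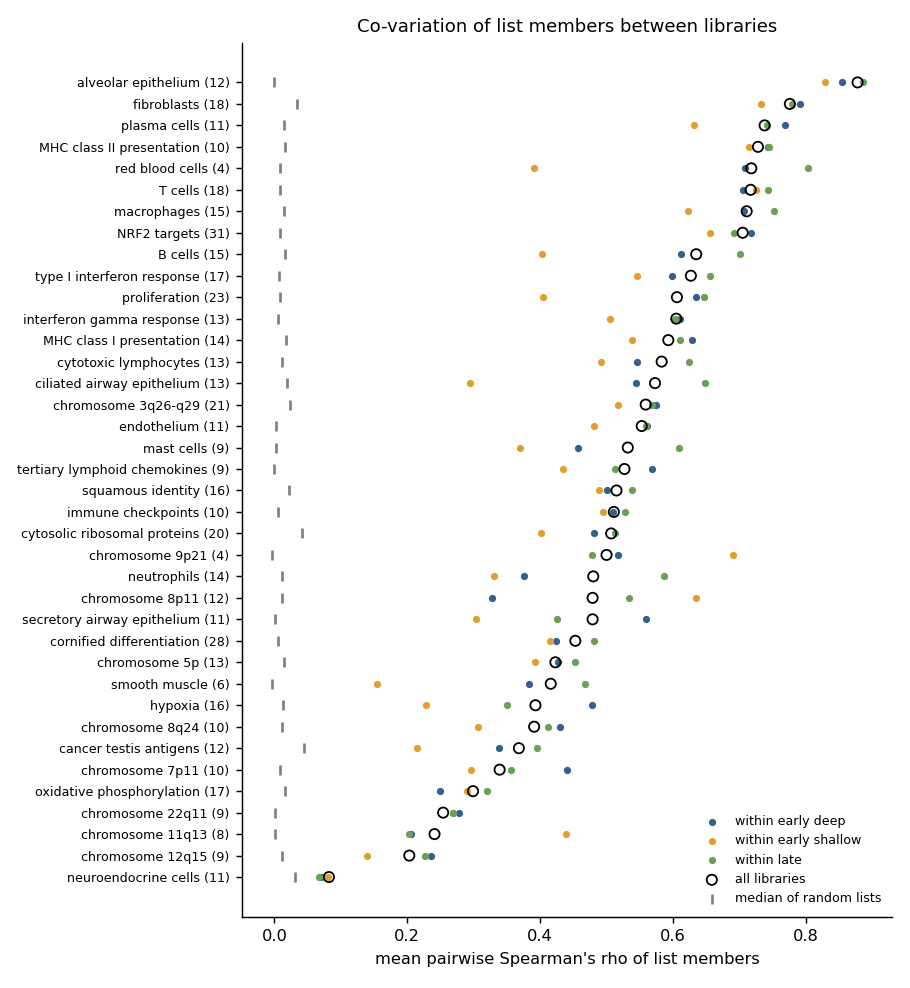
Mean pairwise Spearman correlation of the members of each list across libraries (x axis; open circles for all libraries, coloured dots within the 3 blocks, grey ticks for the median of 10000 random lists), with the number of genes of each list in brackets. All open circles lie right of their grey tick, from 0.082 for neuroendocrine cells to 0.878 for alveolar epithelium.

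Several programmes split the tumours into a lower and an upper cluster. The score of NRF2 targets, genes of glutathione and NADPH metabolism that NRF2 switches on, had 62 libraries in the lower and 54 in the upper cluster (BIC gain 48.1 for 2 components, 2 modes). Of its 31 genes, AKR1B10 had a median of 81.1 CPM with a 5th to 95th percentile from 0.450 to 1368, NQO1 49.4 CPM (3.66 to 354) and SLC7A11 34.4 CPM (1.94 to 396). Upper cluster libraries made up 17 of 45 in the early deep, 6 of 15 in the early shallow and 31 of 56 in the late block (Fisher's exact test, p = 0.193, adjusted 0.495 over the 9 measures with separate clusters). Squamous identity had 13 libraries in the lower cluster and the others in the upper (BIC gain 64.6), and TP63 and SOX2 had 18 and 98 each (BIC gains 56.4 and 11.2). Alveolar epithelium had 49 and 67 (BIC gain 13), ciliated airway epithelium 90 and 26 and cancer testis antigens 69 and 47, while the upper clusters of the 8p11 and 11q13 genes held 14 and 7 libraries. In the cancer testis antigens the upper cluster held 13 of 45, 4 of 15 and 30 of 56 libraries of these blocks (p = 0.0248, adjusted 0.223), which did not pass. The proliferation score had a BIC gain of 52.5, with 21 libraries in the lower component, but only 1 mode, so it did not meet the rule. Neither did the T cells, hypoxia and cornified differentiation scores (BIC gains -5.8, -1.7 and -7.4).

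**Figure D2:**
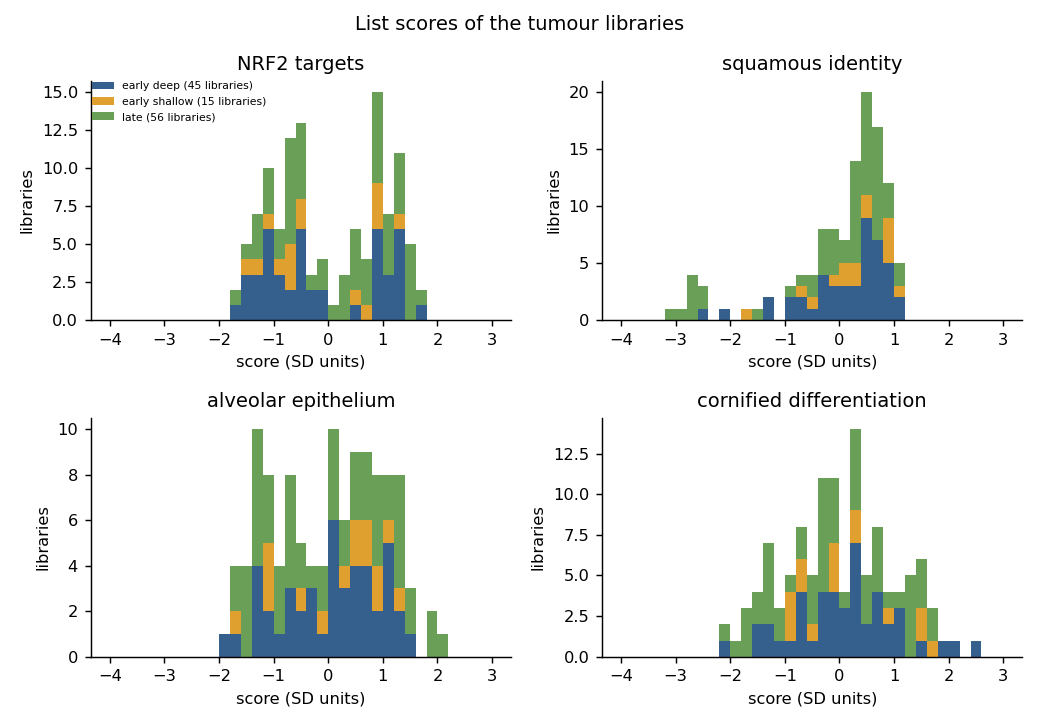
Histograms of 4 list scores over all libraries (x axis, score in SD units; y axis, number of libraries; colours, the 3 blocks, stacked). NRF2 targets, squamous identity and alveolar epithelium fall into clusters, of 62 and 54, 13 and all others, and 49 and 67 libraries, and cornified differentiation has 1 mode.

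NRF2 target expression followed NFE2L2 and KEAP1 transcripts in the lower cluster. There, among 62 libraries, r with NFE2L2 was 0.506 (p = 3e-05, adjusted 0.00013 over 39 correlations) and rho 0.482 (p = 5e-05, adjusted 0.000195). It was 0.513 without the 2 farthest libraries, and 0.625, 0.179 and 0.634 within the early deep (n = 28), early shallow (n = 9) and late (n = 25) blocks. With KEAP1, r was 0.438 (p = 0.00037, adjusted 0.00111) and rho 0.444 (p = 0.0003, adjusted 0.00106), and 0.468 without the 2 farthest (blocks 0.586, 0.344 and 0.352). With the cornified differentiation score, r was 0.468 (p = 0.00017, adjusted 0.000603) and rho 0.414 (p = 0.00083, adjusted 0.0027), and 0.386 without the 2 farthest (blocks 0.480, 0.180 and 0.586). In the upper cluster of 54 libraries, r with NFE2L2 was 0.034 (p = 0.809) and with cornified differentiation -0.167 (p = 0.227). With KEAP1 it was 0.317 (p = 0.0202, adjusted 0.0463; rho 0.256, p = 0.0631, adjusted 0.130) and 0.255 without the 2 farthest (blocks 0.186, -0.358 and 0.340). The B cell score fell with the NRF2 score in the upper cluster, with r = -0.385 (p = 0.00365, adjusted 0.0102; rho -0.402, p = 0.00223, adjusted 0.00669). It was -0.345 without the 2 farthest, and -0.085 (n = 17), -0.890 (n = 6) and -0.420 (n = 31) within blocks, so the early deep block did not show it. In the lower cluster r with B cells was 0.130 (p = 0.314). Whether r differed between the clusters was not tested. The NRF2 score had no adjusted p under 0.05 for r with T cells (r = -0.054 and -0.154), MHC class I (-0.027 and -0.173), MHC class II (-0.050 and -0.265) or proliferation (0.286 and 0.296, adjusted p = 0.0508 and 0.0570) in the lower and upper cluster. For MHC class II in the upper cluster, rho was -0.382 (adjusted p = 0.0121).

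Squamous identity and cornification rose together, and SOX2 rose with TP63 and PIK3CA. In the upper squamous cluster the identity and cornified scores had r = 0.780 and rho = 0.785, with 0.756 without the 2 farthest (blocks 0.775, 0.686 and 0.832). In the 13 libraries of the lower cluster r was 0.697 (p = 0.0105, adjusted 0.0272; rho 0.511, p = 0.0771, adjusted 0.137), but 0.248 without the 2 farthest libraries, on which it rests. Of the blocks, the late one alone held at least 6 of those libraries (r = 0.252, n = 9). SOX2 and TP63 had r = 0.600 and rho = 0.602 in the 91 libraries upper for both (0.605 without the 2 farthest; blocks 0.517, 0.564 and 0.762). SOX2 and PIK3CA are neighbours on chromosome 3q, which also holds TP63. SOX2 and PIK3CA had r = 0.504 and rho = 0.505 in the 98 libraries of the upper SOX2 cluster (0.507 without the 2 farthest; blocks 0.509, 0.603 and 0.504), and -0.006 in the lower 18 (p = 0.983). Copy number was not analysed here, so its part in either relation was not tested. For the 3 pairs of upper clusters, p was 1e-05 for r, the smallest that 100000 resamples give (adjusted 4.88e-05), and 1e-05 or 2e-05 for rho. SOX2 and TP63 in the other strata of 7 to 11 libraries had an adjusted p of 0.340 or above. Squamous identity and alveolar epithelium had r of -0.235, -0.215 and -0.075 in 3 strata (n = 10, 46 and 57; adjusted p of 0.268 or above). Cornified differentiation had r = 0.210 with proliferation (p = 0.0233, adjusted 0.0504; rho 0.070, p = 0.456) and 0.012 with neutrophils (p = 0.902).

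With a rising T cell score, the B cell and interferon gamma response scores each rose and the hypoxia score fell. Over all libraries the T cell score had r = 0.724 and rho = 0.704 with the interferon gamma response (0.722 without the 2 farthest; early deep, early shallow and late blocks 0.671, 0.746 and 0.777). With B cells it had r = 0.685 and rho = 0.684 (0.711; blocks 0.646, 0.439 and 0.766). B and plasma cells had r = 0.818 and rho = 0.827 (0.821; blocks 0.835, 0.534 and 0.843). CD274, which encodes a ligand that restrains T cells, followed the interferon gamma response with r = 0.550 and rho = 0.596 (0.601; blocks 0.438, 0.486 and 0.668). T cells and hypoxia had r = -0.521 and rho = -0.509 (-0.490; blocks -0.573, -0.510 and -0.477). For these 5 pairs p was 1e-05 for r and rho, the smallest possible (adjusted 4.88e-05). T cells and neutrophils had r = 0.365 (p = 6e-05, adjusted 0.000234) and rho = 0.415 (p = 1e-05), with 0.377 without the 2 farthest. The early shallow block did not show this relation (blocks 0.409, -0.013 and 0.433). T cells and proliferation had r = -0.232 (p = 0.0127, adjusted 0.0310) and rho = -0.223 (p = 0.0160, adjusted 0.0390), and -0.232 without the 2 farthest (blocks -0.322, 0.051 and -0.210). Hypoxia and oxidative phosphorylation had r = 0.337 (p = 0.00021, adjusted 0.000683) and rho = 0.277 (p = 0.00261, adjusted 0.00727), and 0.302 without the 2 farthest (blocks 0.448, 0.152 and 0.308). With DESeq2 size factors this r was 0.213 (adjusted p = 0.0504), and the block took 16% of the variance of the oxidative phosphorylation score. T cells with fibroblasts (r = 0.102, p = 0.278; rho 0.128, p = 0.169) and hypoxia with neutrophils (r = -0.115, p = 0.220; rho -0.168, p = 0.0723) did not pass.

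**Figure D3:**
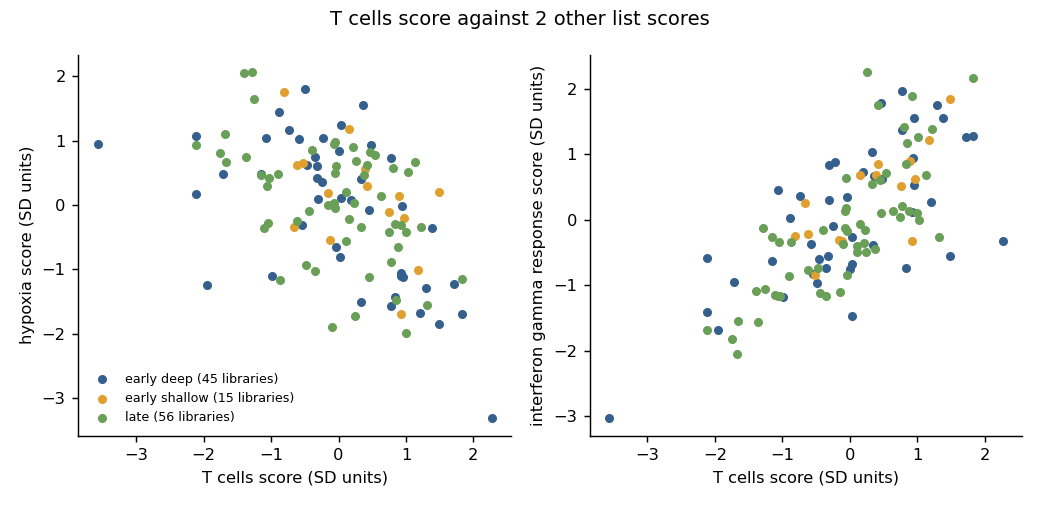
The T cell score (x axis, SD units) against the hypoxia score and the interferon gamma response score (y axes, SD units), 1 point per library, coloured by block. Hypoxia falls (r = -0.521) and the interferon gamma response rises (r = 0.724) with the T cell score, in all 3 blocks.

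Within its clusters, a higher NRF2 score went with more transcripts of 6 of 10 genes of chromosome 7p11 and 4 of 21 of 3q26-q29, and with fewer of 3 of 18 fibroblast genes. The transcribed pseudogene NMRAL2P rose by 3.08 log2 per SD of the score (SE 0.39, adjusted p = 1.36e-08). The glucuronidation enzyme UGT1A6 rose by 2.38 (SE 0.46, adjusted p = 0.000362) and KEAP1 by 0.51 (SE 0.13, adjusted p = 0.00870). Of the 10 genes of 7p11, 6 rose (6 adjusted over the list alone), including the serine synthesis enzyme PSPH (0.91), SUMF2 (0.59) and EGFR (0.85), and limma called PSPH, SUMF2 and CCT6A. The list as a whole rose in camera (adjusted p = 3.9e-06; adjusted p = 0.488 with an estimated correlation). In 3q26-q29, 4 of 21 rose (4 adjusted over the list alone): DCUN1D1, a regulator of protein neddylation, by 1.01 (SE 0.18, adjusted p = 0.00014), ATP11B by 0.93, MCCC1 by 0.85 and ALG3 by 0.62, of which limma did not call MCCC1. That list had an adjusted p = 6.21e-05 in camera, and adjusted p = 0.584 with an estimated correlation. Of 23 proliferation genes, MCM2 (0.67), a replication factor, and PLK1 (0.65), a mitotic kinase, rose (4 adjusted over the list alone; adjusted p = 0.488 with an estimated correlation). Of 18 fibroblast genes 3 fell (10 adjusted over the list alone), among them fibronectin, FN1 (-0.90, SE 0.24), and the contractile actin ACTA2 (-0.76), with an adjusted p = 0.488 with an estimated correlation. Of 18 T cell genes CD8B (-1.66), TRAT1 (-1.23) and LCK (-0.93) fell (14 adjusted over the list alone), 0 of them by limma (adjusted p = 0.584 with an estimated correlation). Of 11 neuroendocrine genes, CHGA, INSM1, NCAM1 and SCG3 fell (6 adjusted over the list alone), 0 of them by limma (adjusted p = 0.488 with an estimated correlation). In all, 349 of 24898 genes rose and 579 fell (edgeR quasi-likelihood test, adjusted p under 0.05 and a slope of at least 0.5), and limma called 375 of them. Limma alone had 513 higher and 171 lower, and edgeR without the count filter 5263 and 3324, so the balance turned. The 12 highest among the more expressed genes included ENSG00000253339, PRB3, SPRR2B, ENSG00000231683, NTS, PLEKHS1, ABCA4, FGFBP1 and CNFN (1.8 to 5.72). Limma called 8 of the 12, 3 of the 12 had most of their CPM in 3 libraries, and SPRR2B, NTS, ABCA4 and FGFBP1 lost edgeR's call without the early shallow block. With the block as a covariate PRB3, ABCA4 and CRNN lost it. The 8 lowest, CPS1, FGB, FGA, CRNN, FABP7, TFAP2B, CGB5 and KRT81 (-7.06 to -4.40), had 90.1% or more of their CPM in 3 libraries each, and limma called 0 of them. Of the lists, 20 moved in camera and 0 did with an estimated correlation, and 6 random reorderings of the score called 14 to 122 genes.

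The cornified differentiation score carried the basal and squamous programme with it, and some T cell, cytotoxic and interferon gamma response genes fell as it rose. Of 16 squamous identity genes 15 rose (15 adjusted over the list alone), among them the desmosomal cadherin DSG3 by 1.75 log2 per SD (SE 0.18, adjusted p = 4.81e-14), KRT14 by 1.8 (SE 0.28, adjusted p = 2.37e-07), PERP by 0.84 (SE 0.08) and TP63 by 0.75 (SE 0.16). This was the 1 list of the 16 that moved in camera to hold with an estimated correlation (adjusted p = 4.78e-09). Among the 12 highest slopes, the cornified envelope gene SPRR2B rose by 3.88 (SE 0.22, adjusted p = 3.76e-31), filaggrin, FLG, by 3.27 (SE 0.25, adjusted p = 8.07e-21) and repetin, RPTN, by 3.25 (SE 0.26). The others of the 12 were PRB3, CRNN, SPRR2G, FETUB, C10orf99, SERPINB2, FGFBP2, the skin cytokine antagonist IL36RN and the proton pump ATP12A (1.92 to 4.17). Limma called 12 of 12, and 6 of them (PRB3, CRNN, FLG, SPRR2G, SPRR2B and RPTN) had most of their CPM in 3 libraries. NFE2L2 rose by 0.56 (SE 0.08, adjusted p = 1.46e-08). Of 31 NRF2 targets AKR1B10, GPX2, CBR1 and ADH7 rose and ABCC2 fell (6 and 1 adjusted over the list alone; adjusted p = 0.313 with an estimated correlation). Of 16 hypoxia genes the glucose transporter SLC2A1 (0.58), NDRG1 (0.78) and the vasodilator ADM (0.56) rose (3 adjusted over the list alone; adjusted p = 0.143 with an estimated correlation). Of 18 T cell genes 6 fell (6 adjusted over the list alone), CD8B (-1.05, SE 0.13, adjusted p = 1.97e-10) and CD3G (-0.55) among them, with an adjusted p = 0.315 with an estimated correlation. Of 13 interferon gamma response genes 6 fell (6 adjusted over the list alone), including the chemokine CXCL11 (-0.78) and UBD (-0.83; adjusted p = 0.346 with an estimated correlation). Of 13 cytotoxic genes 5 fell (5 adjusted over the list alone), including granzyme GZMA (-0.65; adjusted p = 0.313 with an estimated correlation). Of 11 neuroendocrine genes 7 fell (7 fell and 1 rose adjusted over the list alone), and INSM1 (-1.84), NCAM1 (-1.15) and SCG3 (-1.48) did so by limma too. The list did not pass in camera (adjusted p = 0.0602; adjusted p = 0.504 with an estimated correlation). Of 12 alveolar genes 8 fell (12 adjusted over the list alone) but 0 by limma, and the list had an adjusted p = 0.610 with an estimated correlation. In all, 557 of 24901 genes rose and 931 fell, of which limma called 612 (limma alone had 821 higher and 270 lower, the opposite balance; edgeR at a mean CPM of at least 1 had 391 and 447, and without the count filter 3753 and 3904), and 6 random reorderings called 69 to 124. The 8 lowest, FGB, FGA, CGB5, LVRN, CPS1, TFPI2, MYBPC1 and FGG (-4.05 to -1.80), had 69.6% or more of their CPM in 3 libraries each and limma called 0 of them.

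Tumours with a higher T cell score had more transcripts of antigen presentation, cytotoxic, B cell, plasma cell and macrophage genes, and a lower hypoxia programme. All 10 MHC class II genes rose (10 adjusted over the list alone), HLA-DRA by 0.88 log2 per SD (SE 0.07, adjusted p = 1.71e-20) and their regulator CIITA by 0.85 (SE 0.07), as did 12 of 13 cytotoxic genes (GZMK 1.44, NKG7 1.36; 12 adjusted over the list alone). Of 15 B cell genes 14 rose (MS4A1 1.83, SE 0.18, adjusted p = 1.26e-15; 14 adjusted over the list alone), and of 11 plasma cell genes 11 (JCHAIN 1.39; 11 adjusted over the list alone). Chemokines and receptors of tertiary lymphoid structures, lymph node-like aggregates, rose in 8 of 9 (CCR7 1.49, CCL19 1.40; 8 adjusted over the list alone). Of 10 immune checkpoint genes 7 rose (7 adjusted over the list alone), PDCD1 by 1.40 (SE 0.12), LAG3 by 1.07 and TIGIT by 1.05, while CD274 had a slope of 0.00 (SE 0.14, adjusted p = 0.998; limma adjusted p = 0.000399). Of 13 interferon gamma response genes 11 rose (CXCL9 1.19, the tryptophan-degrading enzyme IDO1 1.21; 11 adjusted over the list alone), of 14 MHC class I genes 6 (PSMB9 0.70; 6 adjusted over the list alone) and of 15 macrophage genes 12 (the complement gene C1QA 0.79; 12 adjusted over the list alone). These 9 lists held with an estimated correlation (adjusted p from 7.69e-07 to 0.0118). So did the fall of the hypoxia list (adjusted p = 0.0256), in which BNIP3 (-0.80, SE 0.09, adjusted p = 4.33e-13) and CA9 (-0.66) of 16 fell (2 adjusted over the list alone). Another 18 of the 28 lists that moved in camera did not hold. Among these, all 12 alveolar genes rose (12 adjusted over the list alone), SFTPC by 1.69 (SE 0.52) and the lung lineage factor NKX2-1 by 1.03 (adjusted p = 0.228 with an estimated correlation). The 3q26-q29 list fell (median slope -0.31, camera adjusted p = 4.4e-10; adjusted p = 0.101 with an estimated correlation), with 18 of 21 genes at an adjusted p under 0.05 but 0 past a slope of -0.5 (0 adjusted over the list alone). Type I interferon response genes rose in 2 of 17 (2 adjusted over the list alone; adjusted p = 0.228 with an estimated correlation) and neutrophil genes in 3 of 14 (3 adjusted over the list alone; adjusted p = 0.290 with an estimated correlation). Mast cell genes rose in 5 of 9 (5 adjusted over the list alone; adjusted p = 0.168 with an estimated correlation). Endothelial genes rose in 2 of 11 (2 adjusted over the list alone; camera adjusted p = 0.000119; adjusted p = 0.228 with an estimated correlation). Cornified genes fell in 9 of 28 (10 adjusted over the list alone), such as corneodesmosin, CDSN (-2.16, SE 0.58, adjusted p = 0.00249), and the protease KLK7 (-1.30; adjusted p = 0.315 with an estimated correlation). Squamous identity genes fell in 4 of 16 (SOX2 -0.68, KRT17 -0.71; 5 adjusted over the list alone; adjusted p = 0.228 with an estimated correlation), and cancer testis antigens in 4 of 12 (PRAME -0.62; 5 adjusted over the list alone; adjusted p = 0.381 with an estimated correlation). In all, 1730 of 24911 genes rose and 756 fell, of which limma called 1630, and 6 random reorderings called 66 to 182. At a mean CPM of at least 1, 1051 rose and 391 fell, without the count filter 4623 and 3065, and limma alone had 434 lower. The 12 highest also held the B cell factor SPIB (2.14, SE 0.21), CXCL13 (1.56), MZB1 (1.53), FGA, FGB, UGT2A1, FGG, PGC, LVRN and CGB5. The 8 lowest were MUCL1, a secreted mucin-like protein (-2.73, SE 0.58, adjusted p = 0.000101), CDSN, DSG1, EEF1A2, SPRR2G, which lost the call without the early shallow block, TFAP2B, CRNN and KIF1A. Of these named genes limma called 8 of 12 and 4 of 8, LVRN and CGB5 lost edgeR's call with the block as a covariate, and 10 of the 12 and 6 of the 8 had most of their CPM in 3 libraries.

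As the proliferation score rose, most NRF2 target and squamous identity genes rose, and most endothelial, alveolar, ciliated airway and B cell genes fell. The fit had no cluster term, so the slopes also carry the step to the 21 libraries in the lower component of this score. Of 31 NRF2 targets 25 rose (26 adjusted over the list alone), the glutathione peroxidase GPX2 by 1.62 log2 per SD (SE 0.31, adjusted p = 9.56e-06) and NQO1 by 1.02 (SE 0.19). These slopes run across the NRF2 clusters, and the NRF2 target list had an adjusted p = 0.249 with an estimated correlation. The slopes of squamous identity, alveolar and ciliated airway genes likewise run across the clusters of their own scores. Squamous identity genes rose in 11 of 16 (13 adjusted over the list alone), SOX2 by 1.28 (SE 0.23, adjusted p = 3.75e-06) and TP63 by 1.05 (SE 0.20; adjusted p = 0.196 with an estimated correlation). Of the 3q26-q29 genes 4 of 21 rose (4 adjusted over the list alone): ECT2, which acts in cytokinesis, by 0.88 (SE 0.06, adjusted p = 3.45e-24), ACTL6A by 0.61, TFRC by 0.61 and PSMD2 by 0.51 (adjusted p = 0.163 with an estimated correlation). SKP2, a cell cycle ubiquitin ligase subunit on 5p, rose by 0.69 (SE 0.07). All 12 alveolar genes fell (12 adjusted over the list alone), AGER most (-1.36, SE 0.16, adjusted p = 5.57e-12; adjusted p = 0.163 with an estimated correlation), and so did 7 of 11 endothelial genes (ROBO4 -0.60, SE 0.06; CDH5 -0.54; 7 adjusted over the list alone; adjusted p = 0.0767 with an estimated correlation). B cell genes fell in 12 of 15 (CD22 -0.84; 13 adjusted over the list alone; adjusted p = 0.358 with an estimated correlation), ciliated airway genes in 9 of 13 (HYDIN -0.57; 10 adjusted over the list alone; adjusted p = 0.358 with an estimated correlation) and secretory airway genes in 5 of 11 (SCGB1A1 -0.74; 5 adjusted over the list alone; adjusted p = 0.476 with an estimated correlation). Macrophage genes fell in 5 of 15 (the scavenger receptor MARCO -1.06, SE 0.13; 5 adjusted over the list alone; adjusted p = 0.163 with an estimated correlation), and red blood cell genes in 4 of 4 (HBB -0.61; 4 adjusted over the list alone; adjusted p = 0.334 with an estimated correlation). In all, 1323 of 24906 genes rose and 1505 fell, of which limma called 1839 (853 and 783 at a mean CPM of at least 1, and 4342 and 3463 without the count filter, where more rose than fell), and 6 random reorderings called 35 to 119. The calcium-binding CALB1 (2.79, SE 0.53, adjusted p = 1.16e-05), LINC01206 (2.30), UGT1A7 (1.84), NTS (1.68), LCAL1 (1.58), the calcium channel gene CACNA1B (1.52) and SOST (1.51) were, with GPX2, the 8 of the 12 highest that limma called too. PRB3, CTCFL, MYBPC1 and TKTL1 completed these 12, of which 4 had most of their CPM in 3 libraries. Of the 8 lowest (CGB5, CRNN, UGT2A1, KRT81, TFAP2B, LVRN, AGER and the gastric and alveolar protease PGC) limma called LVRN, AGER and PGC, UGT2A1 lost edgeR's call with the block as a covariate, and 7 had most of their CPM in 3 libraries. Of the 25 lists that moved in camera, 0 did with an estimated correlation.

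**Figure D4:**
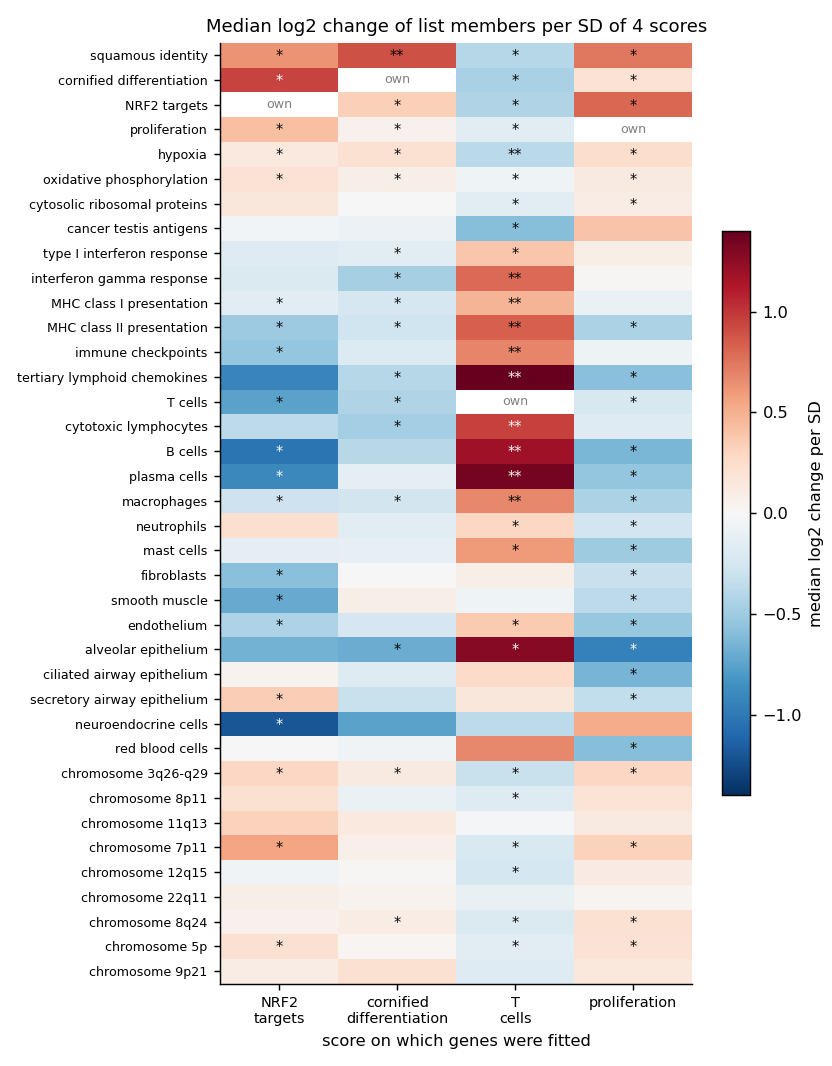
Median log2 change per SD of 4 scores (columns) for the members of each list (lines of the grid; red higher, blue lower; own, the score's own list). A single star marks an adjusted p under 0.05 in camera, which 20, 16, 28 and 25 lists reached from left to right, and 2 stars mark lists that also reached it with an estimated correlation (0, 1, 10 and 0).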

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

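Settings with the block, without the 15 libraries of the early shallow block, with limma or with a mean CPM of at least 1 were chosen after seeing the data. Of 338 alternatives 302 kept the direction and the side of the threshold or, for counts, lay within 1.5 times. Among the correlations 0 reversed in these alternatives. Values within single blocks were not counted among them, and some in the early shallow block had the opposite sign. Higher and lower genes were counted separately, so a turn of their balance was not recorded as a reversal. By limma the balance turned for the NRF2 and cornified scores, and without the count filter for the NRF2 and proliferation scores. For proliferation it also turned at a mean CPM of at least 1. The r of T cells with hypoxia ran from -0.538 to -0.490 and with the interferon gamma response from 0.714 to 0.731, and co-variation held for 38 lists in each of its alternatives. Of the others, 8 gained the threshold. In the lower NRF2 cluster, r with proliferation was 0.315 with median scores, 0.326 given library total and mitochondrial share, 0.361 without the 2 farthest libraries and 0.304 with the block regressed out. In the upper cluster it was 0.350 given total and share. Cornified differentiation with proliferation had r = 0.224 with a prior count of 0.25, 0.207 with median scores and 0.233 without the 2 farthest libraries. Another 7 lost it. For NRF2 targets with KEAP1 in the upper cluster, r was 0.313 with DESeq2 size factors, 0.255 without the 2 farthest libraries and 0.278 with the block regressed out. Squamous identity with cornification in its lower cluster had 0.622 given total and share, 0.248 without the 2 farthest libraries and 0.509 with the block regressed out, and hypoxia with oxidative phosphorylation 0.213 with size factors. The cause was not tested.

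The remaining 21 are counts. With an estimated inter-gene correlation, 0, 1, 10 and 0 lists moved with the NRF2, cornified, T cell and proliferation scores, since members of a list vary together. Without a count filter, genes higher and lower were 5263 and 3324, 3753 and 3904, 4623 and 3065, and 4342 and 3463, in the same order. Genes lower with the NRF2 score were 952 by DESeq2's Wald test. By limma, genes lower with the NRF2, cornified and T cell scores were 171, 270 and 434, and the cause was not tested. At a mean CPM of at least 1, where fewer genes are tested, genes lower with the cornified score were 447, those higher and lower with the T cell score 1051 and 391, and with proliferation 853 and 783. Pairs of single genes have no alternative with median scores, and strata under 8 libraries none that is partial or leaves out 2 libraries. The early shallow block, at a mean of 15573722 counts, limits the genes with low CPM.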

Other observations

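Levels of some genes of other lists follow. Neuroendocrine genes had a median of 0.263 CPM over the list's medians, and the granule protein gene CHGA had a median of 0.308 CPM and a 95th percentile of 28.5. Cancer testis antigens, genes of the germ line, were uneven: MAGEA3 had a median of 0.0588 CPM and a 95th percentile of 26.3, and PRAME 5.42 and 44.8. Of airway genes, the mucin MUC5B had a median of 22.2 CPM with a 5th to 95th percentile from 0.846 to 1803, and FOXJ1, the regulator of cilia, a median of 1.27 CPM. Haemoglobin HBB had a median of 6.60 CPM (0.626 to 103.4). LAMP3, which marks mature dendritic cells and alveolar type II cells, had a median of 211 CPM (35.4 to 935). The fibrinogen genes, which the liver expresses, stood at a median of 0.664 CPM for FGA and 0 for FGB, with 98.3% and 99% of their CPM over all libraries in 3 libraries each, and CPS1, a urea cycle enzyme, had 94.4% in 3.

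The leading direction of variation was not one of the blocks. The first component took 8.73% of the variance and the block explained a share of 0.010 of it, while the next 2 (4.09% and 3.62%) had 0.181 and 0.213. By list, the block took 21.5% of the variance of the score of cytosolic ribosomal proteins, 16% of that of oxidative phosphorylation and 12.4% of that of neuroendocrine genes.

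Tests with the block and those of alveolar tissue were chosen only after the result was seen, as was the NRF2 test on library total and mitochondrial share, and beyond the mix of cells in the pieces no biological explanation was tested, because the labels give 1 group. The score of NRF2 targets had 2 modes (BIC gain 48.1 for 2 components). With block means taken out the gain was 36.1, with library total and mitochondrial share regressed out 32.3, and without AKR1C1, AKR1C2, AKR1C3, AKR1B10, CYP4F3, CYP4F11 and TRIM16L, which share reads with relatives, 39.1, each with 2 modes. These values argue against the blocks, the depth and shared reads as the whole cause. Mutations of NFE2L2, KEAP1 or CUL3 may underlie the upper cluster, a hypothesis left untested because the files hold no variants.

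The hypoxia score fell as the T cell score rose (r = -0.521). A lower share of tumour cells would lower hypoxia genes wherever other cells are many, so fibroblasts, endothelium and macrophages should each have had r of -0.25 or below with hypoxia. Endothelium had -0.323 and macrophages -0.341, but fibroblasts had 0.137 (95% interval -0.046 to 0.312) and missed the prediction. The fibroblast list did not move with the T cell score in camera (median slope 0.08, adjusted p = 0.195). Its r with hypoxia therefore cannot decide about the share of tumour cells. The 3q26-q29 and squamous identity lists fell with the T cell score about as much as the hypoxia list (median slopes -0.31, -0.40 and -0.38). The cornified, NRF2 target and cancer testis lists fell somewhat more (-0.45, -0.42 and -0.60). Proliferation, oxidative phosphorylation and ribosomal protein lists fell less (-0.16, -0.06 and -0.16). A lower share of tumour cells thus remains open as a part or the whole of the cause. The partial r given library total and mitochondrial share was -0.534 (-0.652 to -0.389), and with block means taken out r was -0.529 (-0.648 to -0.383), which argues against both as the whole cause. Given the scores of the 3 cell types the partial r was -0.383 (-0.528 to -0.216), and a link of poorly supplied tissue with fewer T cells may be a candidate explanation that expression alone leaves open.

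Alveolar genes ranged widely between tumours. The block took 0.31% of the variance of their score, and the 10 members other than SFTPA1 and SFTPA2 had a median SD of 3.50 log2 CPM, which argues against the blocks and against reads shared by that pair. If lung alveoli lay inside some tumour pieces, capillary genes should rise with alveolar genes. In the 67 libraries of the upper alveolar cluster the endothelium score had r = 0.727 (95% interval 0.590 to 0.824; rho 0.708; p = 1e-05, adjusted 5e-05 over 5 correlations; blocks 0.650, 0.855 and 0.783; 0.658 without the 2 farthest), so alveolar tissue in the pieces may be the source there. In the 49 libraries of the lower cluster r was 0.059 (-0.226 to 0.335; p = 0.687), where the interval is too wide to decide, so alveolar tissue and tumour cells with alveolar genes cannot be told apart.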
